A study of Mus musculus with 19 samples.

How the data were processed

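RNA from cortices of individual mouse fetuses was hybridised to Affymetrix arrays, 1 per fetus. Per the labels' protocols, the study had 20 pregnant mice in 4 groups of 5, fetal sex was typed by PCR, and 1 array was removed for poor quality, which left 19. Per the labels' protocols the array was a rat design, but the probe sets and gene names of the deposited tables are those of mouse, and the mouse names were used. Per the labels the goitrogen is named as propylthiouracil in some fields and as perchlorate with methimazole in others.

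The values analysed are probe set intensities on a linear scale that the authors had already summarised and normalized before they deposited them. They ranged from 8 to 29808.5. Per the submitters' processing notes RMA and MAS5 were used, with no version, and which of them made the values is not given in the sources used here. A second table holds the authors' signed fold changes, a score above 1 for a rise and below −1 for a fall, for 6 contrasts of the groups. It also holds the authors' permutation p-values, deposited raw and adjusted, and 1 present or absent call per probe set, per the file headers. Its folds equalled the differences of group means to within 0.0072 on the log2 scale. It was used for the values named as the authors' and, as an alternative, for its present calls (28420 probe sets).

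Of 45101 probe sets 64 controls were left out. The deposited table gave no symbol for 6167, 1 for 36867 and several for 2003. Probe sets with several symbols or none were to be left out, by a rule set before the data were examined. Of the 2003, 33 were kept because all their symbols are names of 1 current gene, and Klf9 is among these. This exception was set after the table had been seen, and the choices without it and with a looser version (1021 probe sets) are alternatives. Symbols were updated through a gene table of assembly GRCm38.p6, used for names only, so no coordinates are given. A probe set also needed exactly 1 current gene in that table, which left out some with 1 deposited symbol. All probe sets left out by these rules, controls aside, are called probe sets without a single gene name below. The gene value was that of the probe set with the highest mean over the 19 arrays, which gave 17730 genes from 33598 probe sets, 8681 of them with more than 1. Dio3 was not measured.

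Values were transformed to log2(value + 32), so changes of dim genes are understated. All 19 arrays entered 1 fit of group means in limma 3.58.1 (R 4.3.3) with lmFit and eBayes, 15 residual degrees of freedom and Benjamini-Hochberg adjustment over all genes, and an adjusted p under 0.05 was the threshold. Log2 changes are given with their standard error. Adjusted p values are limma's, two-sided, unless the authors' table is named. The 6 contrasts were each treated group against control, hypo_plus against hypo, hypo_plus against hyper, and the difference of both hormone responses.

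Before the data were examined, 32 gene lists of cell types, pathways and thyroid hormone genes were fixed, together with the alternatives and the rule for the genes named. The rule took the 10 largest rises and the 10 largest falls among genes past the threshold, or, where fewer than 10 passed, all of these and the 5 of smallest p in each direction. It also took list members past the threshold, up to 6 per list, and 12 preset thyroid hormone genes. Only some of the genes it gives are named, and 1 preset gene is not reported here. Lists were tested with camera and an estimated correlation, adjusted over the lists of a comparison, and with a preset correlation and fry as alternatives. Lists for hypothalamus, dorsal cortex, imprinted and nuclear-retained transcripts were added later.

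Arrays were checked for duplicates. Pairwise correlations were 0.9704 to 0.9902 and no pair was identical, the smallest median absolute log2 difference being 0.1596. The alternatives changed the probe set rule, the normalization, the pseudocount, the array weights, the prior, the threshold and the arrays used, and 6 of them were chosen after the data had been seen. The fit was tested on simulated data for each comparison, with independent noise and some genes changed by 0.5, 1 or 1.5. These data had no structure shared between genes or arrays, so recovery in the real data may be lower. Most of the changed genes moved by 1 or 1.5, which eases the unadjusted p needed to pass. Recovery would be lower where fewer genes change. In hypo_plus against hypo 84.1% of genes changed by 0.5 and 98.3% of genes changed by 1 on the log2 scale were recovered, and in hyper against control 71.9% and 100%.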

Results

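RNA from the cerebral cortex of fetal mice on gestational day 16 was measured on 19 arrays that carried 45101 probe sets. Pregnant C57BL/6 dams drank water with or without goitrogens, drugs meant to block the maternal and fetal thyroid. The water was given for 3 days from gestational day 13. Each dam received 1 injection 12 hours before it was killed. The control group (5 arrays) had sucrose water and vehicle. The hypo group (5 arrays) had goitrogen water and vehicle. The hypo_plus group (5 arrays) had goitrogen water and 25 µg T4 with 2.5 µg T3 per 100 g body weight, a dose meant to restore normal hormone levels. The hyper group (4 arrays) had sucrose water and 100 µg T4 with 10 µg T3 per 100 g, so its dose was 4 times that of hypo_plus. The descriptions name the goitrogen in different ways: the title speaks of propylthiouracil, whereas the treatment text gives 1% perchlorate with 0.025% methimazole. The group is therefore called goitrogen here. Each array was made from 1 fetus described as female, and whether any fetuses shared a dam was not stated, so p-values measure the spread between these fetuses. Array medians lay between 73.1 and 106 signal units, and the number of arrays limits the precision.

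Transcripts of the sex chromosomes differed from the description on 2 arrays. Xist, the RNA that silences 1 X chromosome in females, read 68.8 on hypo_plus replicate 1 and 97.2 on hyper replicate 4, against 3145.1 to 8226.4 on the other 17 arrays. Ddx3y, encoded on the Y chromosome, read 695.9 and 546.7 on these arrays and at most 11.3 on the others. Eif2s3y, Kdm5d and Uty were high on the same arrays. Counts without both arrays, chosen after the data were seen, stand beside the comparisons they move.

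**Figure D1:**
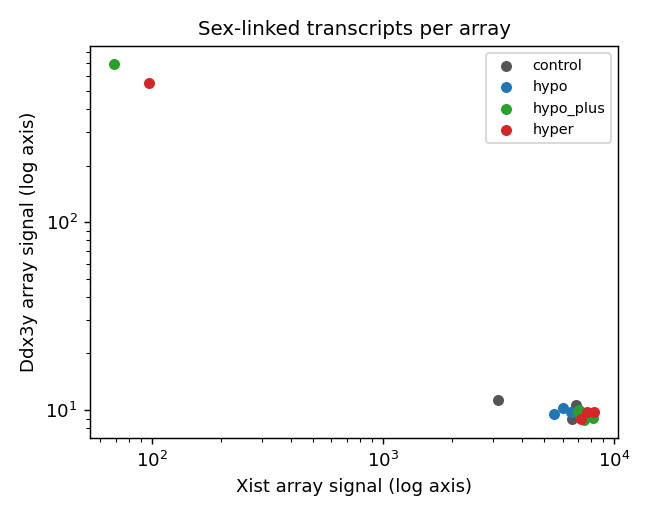
Signal of Xist (horizontal, log axis) against Ddx3y (vertical, log axis), 1 point per array, coloured by group. The arrays hypo_plus replicate 1 and hyper replicate 4 lie at Xist 68.8 and 97.2, apart from the other 17.

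The high hormone dose in animals without goitrogen moved few genes past the threshold with limma, and among these the largest rises were in Klf9 and Sema3c. Klf9, a transcription factor gene that is a direct target of thyroid hormone receptors, rose from a signal of 130.1 ± 24 (SD, n = 5) in controls to 555.9 ± 142.6 (SD, n = 4), a log2 change of 1.84 ± 0.13 (SE) with adjusted p = 3.98e-07. Sema3c, which encodes a secreted axon guidance protein, rose by 1.35 ± 0.10 (adjusted p = 9.09e-07), from 926.6 ± 81.9 to 2408.7 ± 176.3. In both genes 4 of 4 hyper arrays lay above all arrays of the other groups. Sorl1, a sorting receptor of the endosome, Rgs6, a regulator of G protein signalling, Rflnb and Ranbp10 also rose, with log2 changes of 0.86, 0.88, 0.72 and 0.35. So did Dbp, a transcription factor under control of the circadian clock (0.93 ± 0.15, adjusted p = 0.0167). Lin7c, a scaffold gene of cell junctions, fell by 0.45 (adjusted p = 0.0287). In all, 8 of 17730 genes passed, 7 up and 1 down, and 1421 had an unadjusted p under 0.05. Among genes of smallest p that missed the threshold were Aldh2 (−0.45, adjusted p = 0.0522), Prrc2c (0.67, adjusted p = 0.0576) and Kdm6b (0.73, adjusted p = 0.0751).

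Among 19 measured genes of the list induced by thyroid hormone, Klf9 rose over all genes, and 2 rose adjusted over the list alone, the other being Camk4, a calcium-dependent kinase gene (0.54, list-alone adjusted p = 0.00801). Hr, a corepressor gene often used as a hormone reporter, had a log2 change of 0.27 ± 0.13 (adjusted p = 0.649), and Shh, Mbp, Nrgn, Thra, Thrb and Ttr lay between −0.27 and 0.29 without passing. Dio2, the enzyme that activates T4, had a value of 0.00 (adjusted p = 0.998). The 7 genes of the hormone-repressed list had a median of −0.14 and the 8 astrocyte genes −0.13, and both lists had adjusted p = 0.189 with an estimated correlation. Gfap, an astrocyte filament gene (−0.34), and Syp, a synaptic vesicle gene (−0.43), passed only when adjusted over the list alone.

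The count of 8 became 5 without control replicate 3 or 5 or without hyper replicate 3 or 4, 13 without control replicate 1 and 18 without control replicate 4. Without both arrays with Y-linked signal it was 5. Taken singly, 79 probe sets passed, and 51 genes had at least 1 of them. The authors' table lists 248 probe sets with an adjusted permutation p-value under 0.05, 159 up and 89 down. With quantile normalization 15 genes passed, 12 up and 3 down, and with each array centred on its median 5 passed, 5 up and 0 down. Klf9 and Sema3c passed in every alternative in which they were measured, 35 and 36 settings, although Klf9 had 0.90 with the mean of probe sets. The call of Ranbp10 was lost in 19 of 36 alternatives (0.08 with the mean of probe sets), that of Lin7c in 14, of Dbp in 9 of 35, of Sorl1 in 2, and of Rgs6 and Rflnb in 1 each.

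**Figure D2:**
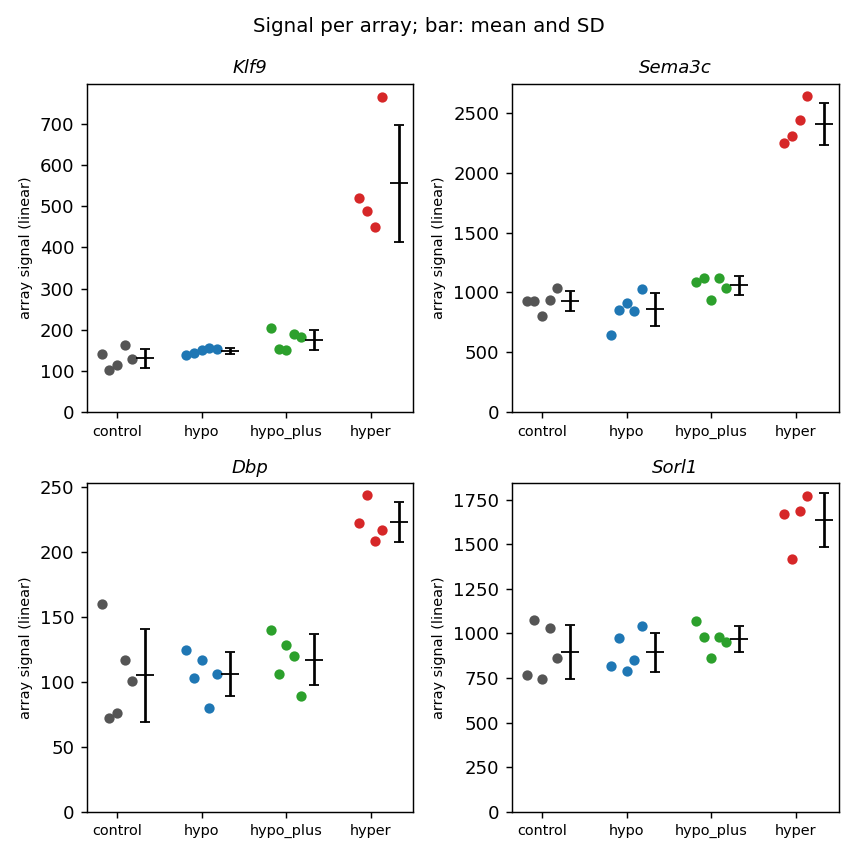
Array signal (linear, vertical) of Klf9, Sema3c, Dbp and Sorl1 in the 4 groups, 1 point per array, with mean and SD. The hyper arrays of Klf9 lie between 449.4 and 765.2, above the highest other array at 205.2.

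Goitrogen alone, given for 3 days, gave no gene past the threshold against control with limma. The genes of smallest p included Zfp69, a zinc finger gene, at 0.85 ± 0.16 (adjusted p = 0.113), and Cfdp1, a chromatin gene, at −0.41 ± 0.07 (adjusted p = 0.113). Ndufs1, a subunit of respiratory complex I, had a log2 change of −0.35 (list-alone adjusted p = 0.00231, over all genes 0.113). Ebf1 and Rarb, transcription factor genes of the striatum, had −0.41 and −0.30, with list-alone adjusted p of 0.00512 and 0.00653. In the striatum list 1 of 12 genes had a positive value, and 1 of 17 in the list of GABAergic interneurons. All 8 genes of hippocampus and cortical hem were positive, with a median of 0.247. Against the same controls 7 of 8 were positive in hypo_plus (median 0.224) and 6 of 8 in hyper (median 0.109). In hypo against control the striatum, GABAergic and hippocampus lists had adjusted p of 0.506, 0.85 and 0.414 with an estimated correlation. In the list of cholesterol synthesis 3 of 21 genes fell when adjusted over the list alone, among them Cyp51 and Msmo1 (−0.34 each), and the list had adjusted p = 0.598 with an estimated correlation. Thyroid hormone genes moved little, with Klf9 at 0.16 ± 0.12, Hr at 0.10 ± 0.12 and Dio2 at 0.28 ± 0.14. In 10 of 11 choroid plexus genes the change was positive, with a median of 0.48 and adjusted p = 0.506 with an estimated correlation. This was not particular to goitrogen. Against the same controls 9 of 11 were positive in hypo_plus (median 0.382) and 9 of 11 in hyper (median 0.403). The list scores of control replicates 1 to 5 were 0.461, −0.659, −1.008, 0.116 and −0.32. Ttr, the carrier of thyroid hormone made by the choroid plexus, ranged from 5282.4 to 16947.4 among the controls.

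The count was 0 of 17730, with 1757 genes at an unadjusted p under 0.05. The authors' deposited table lists 50 probe sets with an adjusted permutation p-value under 0.05 for this comparison, where limma on each probe set called 0. With a pseudocount of 100 limma called 4 genes, and it called 3, 2 and 1 without control replicate 2, hypo replicate 1 and hypo replicate 5. In simulated data 76.8% of genes changed by 0.5 on the log2 scale were recovered for this comparison. Those data held many changed genes, which eases the unadjusted p needed to pass. The real comparison called 0, so this share does not tell how many such changes were missed.

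Hormone given under goitrogen changed 282 genes against goitrogen alone, the most of the 6 comparisons in the planned fit but not with median centring, without hypo replicate 1, or at an unadjusted p under 0.05 with a fold of 1.5. Zfhx3, a transcription factor gene of neuronal differentiation, rose by 1.43 ± 0.30 (adjusted p = 0.0262), from 490.1 ± 242.3 in hypo to 1289.3 ± 288.8 in hypo_plus (SD, n = 5 each). Malat1, a nuclear non-coding RNA, rose by 1.17 ± 0.17 (adjusted p = 0.00379). Taf15, an RNA-binding protein gene, and Peg3, a paternally expressed imprinted gene, rose by 1.09 and 1.08. Prrc2c (1.07 ± 0.12, adjusted p = 0.000211), Cap1, an actin regulator, and the histone demethylase gene Kdm6b rose as well. For Zfhx3, Malat1, Taf15 and Prrc2c 5 of 5 hypo_plus arrays lay above all hypo arrays. Ndrg1, a gene induced by low oxygen, fell by 0.68 (adjusted p = 0.0111), with 5 of 5 hypo_plus arrays below all hypo arrays. Fezf2, which specifies neurons of the deep cortical layers, fell by 0.80 (adjusted p = 0.0352). Nr4a3, a nuclear receptor gene, Cntn2, an axonal adhesion gene, Sstr2, a somatostatin receptor gene, and Nfib fell by 0.86, 0.79, 0.72 and 0.60. Of the 282 genes 184 rose and 98 fell.

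Genes that pattern the ventral forebrain were among those that rose, while 0 of 9 dorsal cortex genes, a list added after the data were seen, had a positive value (median −0.33, adjusted p = 0.243 with an estimated correlation). The dorsal score of hypo replicate 4 was −0.425, against 0.163 to 0.498 on the other hypo arrays, and the hypo_plus arrays ranged from −0.434 to 0.134. In the list of striatum and ganglionic eminence 2 of 12 measured genes rose, Six3 (0.54 ± 0.12, adjusted p = 0.0293) and Ebf1 (0.40 ± 0.10, adjusted p = 0.0449), and 6 rose adjusted over the list alone, Tac1, Isl1, Drd2 and Gsx2 being the others. The list median was 0.21, and its adjusted p was 0.419 with an estimated correlation. Dlx2, a homeobox gene of interneuron progenitors, was the 1 of 17 GABAergic genes that rose (0.76 ± 0.15, adjusted p = 0.0154), while 15 of 17 had a positive value and the list had adjusted p = 0.56 with an estimated correlation. Part of these rises started from low values in hypo. Against control, the striatum median was −0.186 in hypo and 0.027 in hypo_plus, and the GABAergic median −0.175 and 0.124. Mean signals in control, hypo and hypo_plus were 549, 401.6 and 538.1 for Ebf1, so it was near control in hypo_plus. Six3 (230.2, 223.3 and 338.8) and Dlx2 (1041.7, 913.2 and 1554.8) had higher means in hypo_plus than in control. Ptch1, the receptor and target of sonic hedgehog, rose by 0.65 ± 0.12 (adjusted p = 0.0111), and Shh itself had 0.59 ± 0.16 (adjusted p = 0.0632, list-alone 0.00516). That list of 8 genes had adjusted p = 0.811 with an estimated correlation. Six3 read −0.09 where only probe sets with 1 deposited symbol were used.

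Other groups had single members that passed. Of 10 deep layer genes Fezf2 fell, and Crym, a binding protein of thyroid hormone in the cytosol, had −0.89 ± 0.25 (adjusted p = 0.0839, list-alone 0.0125), while Foxp2 had 0.45 in the other direction. Cux2, a gene of upper layer neurons, rose by 0.42 (adjusted p = 0.0455). Cnp, a myelin enzyme gene, rose by 0.55 (adjusted p = 0.0176), and Olig1 and Olig2, which specify oligodendrocytes, had 0.49 and 0.41 with list-alone adjusted p of 0.0314 and 0.04. Part of these differences came from low values in hypo. Mean signals in control, hypo and hypo_plus were 503.8, 380.5 and 572.4 for Cnp. They were 429.6, 368.2 and 527.1 for Olig1, and 230.6, 194.2 and 268.2 for Olig2. Of 14 hypoxia genes Ndrg1 and Pdk1 fell. The list tests of deep layers (0.862), oligodendrocytes (0.56) and hypoxia (0.862) did not pass, given as adjusted p with an estimated correlation. Among hormone genes Klf9 had 0.20 ± 0.12 (adjusted p = 0.474) and Hr −0.19 ± 0.12 (adjusted p = 0.505). Dio2 had −0.41 ± 0.14 (adjusted p = 0.151, list-alone 0.0351), against hypo arrays of 39.7 to 83.

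With each probe set on its own 1421 probe sets passed, 913 up and 508 down, and 919 genes had at least 1 of them. The authors' table lists 2181 probe sets with an adjusted permutation p-value under 0.05, 1370 up and 811 down. The count of 282 was 85 without hypo_plus replicate 4, 113 without hypo_plus replicate 3, 118 without hypo_plus replicate 5 and 173 without hypo_plus replicate 1. Without hypo replicates 1, 2, 3, 4 and 5 in turn it was 140, 185, 127, 473 and 135. Without both arrays with Y-linked signal it was 167, of which 144 were among the 282. Quantile normalization gave 441 genes, 225 up and 216 down, and median centring 36, 11 up and 25 down. Malat1, Taf15, Peg3, Cap1, Prrc2c and Ndrg1 passed in every alternative in which they were measured, although with the mean of probe sets Malat1 had 0.57, Taf15 0.65, Peg3 0.31 and Prrc2c 0.41. The call of Cux2 was lost in 24 of 36 alternatives (0.05 with the mean of probe sets), 16 of them with 1 array left out. Cntn2 lost it in 19, Ebf1 in 17, Sstr2 in 15, Nfib and Pdk1 in 13, Fezf2 in 11, Six3 in 10, Nr4a3 in 8 and Zfhx3 in 7.

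**Figure D3:**
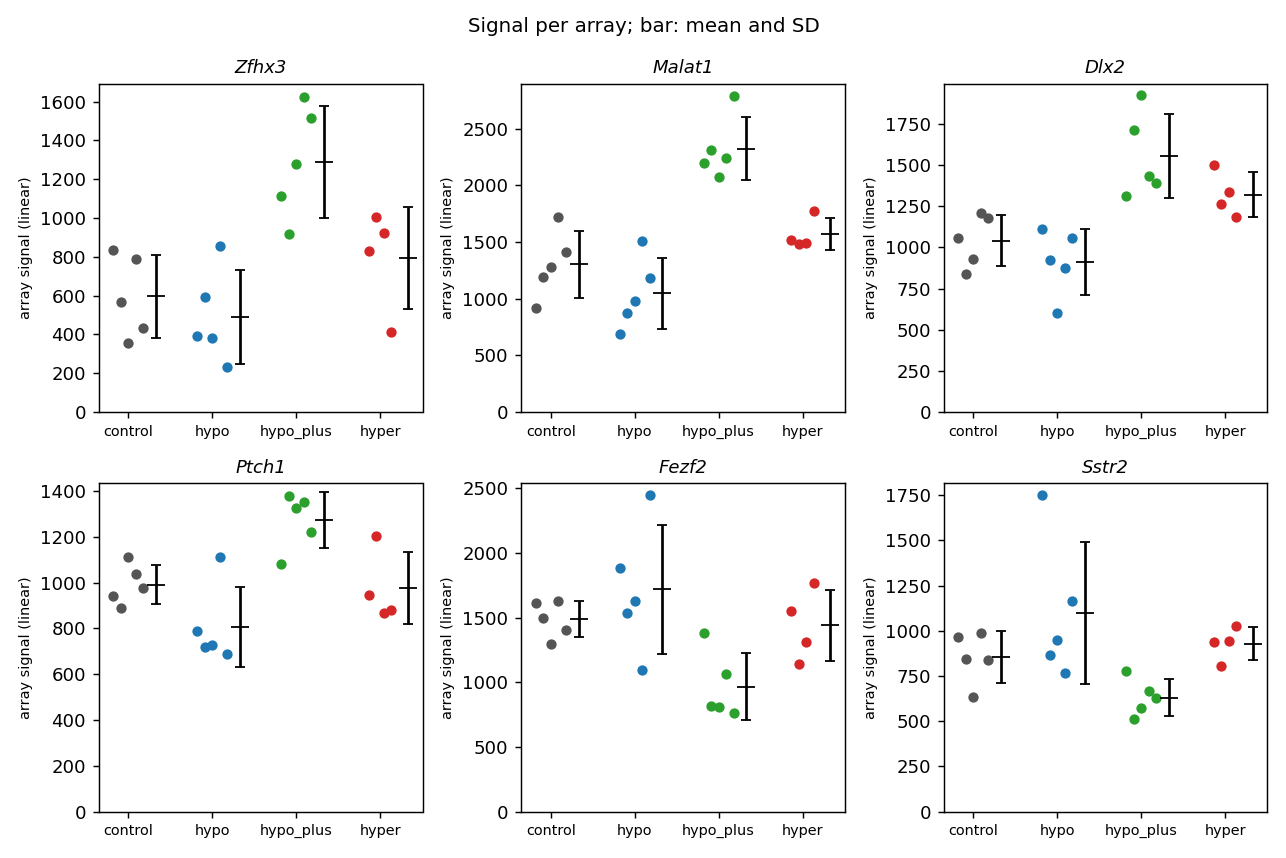
Array signal (linear, vertical) of Zfhx3, Malat1, Dlx2, Ptch1, Fezf2 and Sstr2 in the 4 groups, 1 point per array, with mean and SD. Hypo_plus arrays lie between 1310.1 and 1928.6 for Dlx2, above the highest hypo array at 1114.6.

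Compared with control, 75 genes fell and 25 rose in the hypo_plus cortex, a balance that turned in some settings. Id2, an inhibitor of differentiation, fell by 0.73 ± 0.14 (adjusted p = 0.0344). Tpst1, a protein sulphation enzyme gene, and Rem1, a small GTPase gene, fell by 0.51 and 0.57 (adjusted p = 0.0112 each), with 5 of 5 hypo_plus arrays below all controls. Cryab, a small heat shock protein gene, fell by 0.57. Pafah1b1, the lissencephaly gene of neuronal migration, had −0.26 (adjusted p = 0.0344), while of its 4 other probe sets 2 passed in the same and 1 in the opposite direction, and the call was lost in 14 of 36 alternatives, with −0.05 for the mean of probe sets. Taf15 rose by 1.00 ± 0.16 (adjusted p = 0.0159), Malat1 by 0.84 ± 0.17 and Prrc2c by 0.79 ± 0.12. Ric3, an assembly factor of acetylcholine receptors, and Tet1, a DNA demethylation enzyme gene, rose by 0.71 and 0.60. Of the neuronal migration list Lrp8 and Dab1, which transmit the reelin signal, fell when adjusted over the list alone (−0.23 and −0.42). Klf9 had 0.36 ± 0.12 (adjusted p = 0.182).

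In this comparison 100 genes passed, and 2441 had an unadjusted p under 0.05. With each probe set on its own 1400 probe sets passed, 544 up and 856 down, and 913 genes had at least 1 of them. The authors' table lists 1923 probe sets with an adjusted permutation p-value under 0.05, 818 up and 1105 down. With limma no gene passed without control replicate 3. The count was 51 and 16 without control replicates 1 and 5, 13, 9, 16 and 12 without hypo_plus replicates 2, 3, 4 and 5, 58 and 64 without hyper replicates 2 and 3, and 171 without hypo replicate 1. Quantile normalization gave 75 genes, 44 up and 31 down, and median centring 41, 3 up and 38 down, with the median of all genes at −0.12 after centring. A pseudocount of 1, or only the arrays compared, gave 3 up and 2 down, and an unadjusted p under 0.05 with a fold of 1.5 gave 32 up and 6 down. Of probe sets without a single gene name 294 rose and 68 fell. The call was lost in 20 of 36 alternatives for Tet1, in 15 of 35 for Cryab, in 13 for Malat1, in 12 for Id2 and in 4 for Taf15, which had 0.36 with the mean of probe sets. Prrc2c, Ric3 and Tpst1 lost it in 3 and Rem1 in 1, and Prrc2c had 0.23 with the mean of probe sets.

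The comparison of both hormone-injected groups differs in goitrogen and in dose. Klf9 was lower in hypo_plus than in hyper by a log2 change of −1.48 ± 0.13 and Sema3c by −1.16 ± 0.10 (adjusted p = 1.08e-05 each), with all 5 hypo_plus arrays below all 4 hyper arrays. Sorl1 (−0.74), the proto-oncogene Mycn (−0.48), Tpst1 (−0.45), the ephrin receptor gene Epha3 (−0.43) and Mllt6 (−0.35) were lower too. Hrh3, a histamine receptor gene, and Pi16 were higher by 0.62 and 0.57. Of 14 hypoxia genes 6 fell adjusted over the list alone, among them Ndrg1 (−0.55), Hk2 (−0.40) and Ldha (−0.25), genes of sugar use and the oxygen response, and the list had adjusted p = 0.553 with an estimated correlation. In all 9 genes passed, 2 up and 7 down, and 2182 had an unadjusted p under 0.05. The authors' table lists 49 probe sets with an adjusted permutation p-value under 0.05, 15 up and 34 down, where limma on each probe set called 17.

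The count of 9 was 14 without control replicate 1, 4 without control replicate 3 or 5, 16 without hypo replicate 4 or hypo_plus replicate 1, 4, 3, 5 and 4 without hypo_plus replicates 2, 3, 4 and 5, 3 without hyper replicate 1 or 3, and 2 without hyper replicate 4. It was 2 without both arrays with Y-linked signal. With quantile normalization 4 passed and with median centring 3, all of them lower. Klf9 and Sema3c never lost the call, although Klf9 had −0.74 with the mean of probe sets. Mllt6 lost it in 24 of 36 alternatives, Pi16 in 22 of 35, Mycn and Tpst1 in 18, Hrh3 in 15, Sorl1 in 7 and Epha3 in 5.

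The title of the series states that goitrogen strengthens the response to hormone. The difference of the responses, hypo_plus minus hypo against hyper minus control, was tested directly, with the dose of the first 4 times lower. Klf9 responded less under goitrogen at the lower dose, with a difference of −1.65 ± 0.18 (adjusted p = 0.000431), and so did Sema3c, at −1.04 ± 0.14 (adjusted p = 0.00693). With all arrays 2 genes passed, 0 up and 2 down, and 1391 had an unadjusted p under 0.05. Epha3 (−0.50, adjusted p = 0.0691), Rgs6 (−0.92, adjusted p = 0.07) and Peg3 (1.18, adjusted p = 0.158) did not pass. Ptch1 and Shh had differences of 0.68 and 0.86 with list-alone adjusted p = 0.00547 each, and their list did not pass with an estimated correlation. The count was 25 without hypo replicate 4 (18 up, 7 down), 4 without control replicate 2 (1 up, 3 down) and 4 without control replicate 4 (0 up, 4 down). It was 11 with array weights (6 up, 5 down) and 231 at an unadjusted p under 0.05 with a fold of 1.5 (149 up, 82 down), so the balance of directions depended on the setting. It was 1 without both arrays with Y-linked signal and 1 with median centring, and Sema3c lost its call in both settings. Klf9 passed in all 34 settings and had −0.76 with the mean of probe sets. In simulated data with independent noise 27.4% of differences of 0.5 and 94.1% of differences of 1 on the log2 scale were recovered. Those data held many changed genes, so recovery with the 2 genes called here may be lower.

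**Figure D4:**
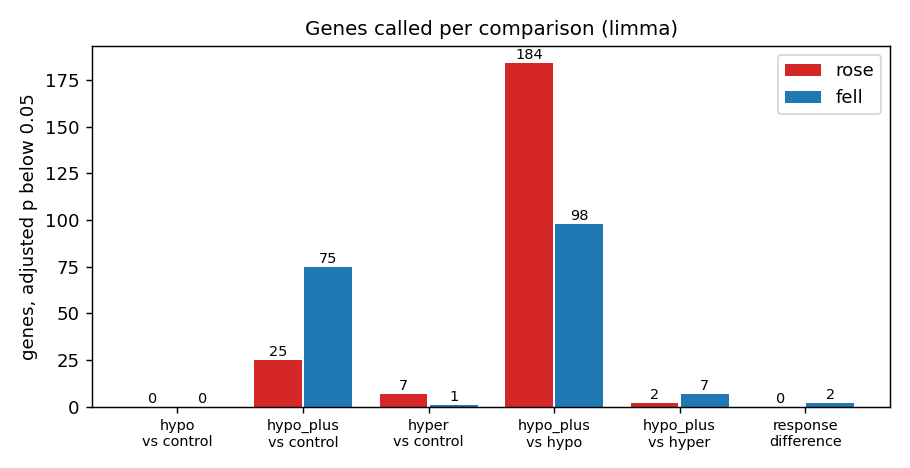
Genes past an adjusted p of 0.05 with limma (vertical, count) in the 6 comparisons, split into genes that rose and fell. The count is 184 up and 98 down for hypo_plus against hypo, and 7 up and 1 down for hyper against control.

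Across all 17730 genes the hormone response under goitrogen and that without it, which share no array, had Pearson r = 0.181 and Spearman rho = 0.197, with a covariance of 0.00443. Genes are not independent replicates, and 10 of 100 splits of the hyper and control arrays gave as high an r, up to 0.236. Of the 282 genes called under goitrogen, 212 (75.2%) had the same sign in hyper against control, where random splits of the hyper and control arrays gave 17.7% to 81.9%. The genes that rose had a median of 0.45 under goitrogen and 0.12 without it. Those that fell had −0.38 and −0.06. These genes were chosen because they passed under goitrogen, and that choice alone enlarges their change there. The medians therefore cannot show whether the response was stronger under goitrogen. The number called in both was 1, where independent lists give 0.127. The correlation was 0.09 without hypo replicate 4, 0.104 without hypo_plus replicate 1 and 0.102 without hyper replicate 2.

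Comparisons that share arrays need a chance value. Hypo_plus and hyper, each against the same controls, shared 2 risen genes and 1 fallen gene, where independent lists give 0.00987 and 0.00423 and simulated unchanged groups gave 0.01. Independent lists ignore the shared arrays, and unchanged groups yield almost no called genes by construction. For shared calls, here and below, neither value can tell whether they exceed what shared arrays give. The r across genes of these 2 contrasts was 0.431, and the simulated groups gave 0.471, while the covariance was 0.00951 against 0.00673. With the controls split into 2 and 3 arrays, the mean r over 10 splits was 0.06, from −0.231 to 0.271. The contrasts of hypo_plus with control and with hypo shared 19 risen and 22 fallen genes, where independent lists give 0.259 and 0.415, and had r = 0.664 against a simulated 0.501 and a covariance of 0.0173 against 0.00676. With the shared hypo_plus arrays split into 2 and 3, the mean r was 0.332, from 0.108 to 0.452.

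Of 192 tests of a gene list, 32 lists in 6 comparisons, 0 passed with camera and an estimated correlation, and 10 had an unadjusted p under 0.05. With a preset correlation of 0.01, 25 passed, among them GABAergic genes and striatum in hypo_plus against hypo, and with fry 1 passed.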

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

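The tests of the Y-linked signal and of the probe sets without a single gene name, and those of the hormone and of the array with Y-linked signal as sources of the regional pattern, were chosen after the result was seen. The test of the dissection with hypothalamus and dorsal cortex lists was chosen before its result was seen.

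Of 244 sets of values in groups of 4 or 5 arrays, 21 held an array far from the others, where chance gives about 1 in 20. Sex-linked genes account for the excess, and the far values of the other genes and lists are about as frequent as chance gives. Among signals, Dio2 read 39.7 on hypo replicate 4 (others from 68.6), Ttr 9750.7 on hyper replicate 1 (others from 15549.8), Ranbp10 625.8 on hyper replicate 3, Mllt6 700 on control replicate 1 and Xist 3145.1 on control replicate 1. Among list scores, the median log2 deviation of a list's genes, synapse genes had −0.298 on hypo replicate 1 and −0.205 on hyper replicate 4. Oligodendrocyte genes had −0.169 on hypo replicate 5, pericyte genes −0.239 on hypo_plus replicate 2, heat shock genes −0.233 and clock genes 0.279 on hypo replicate 1.

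Sex-linked signals on 2 arrays described as female made up 10 of the 21: on hypo_plus replicate 1 and hyper replicate 4 the signals were 68.8 and 97.2 for Xist, 695.9 and 546.7 for Ddx3y, 504.4 and 506.2 for Eif2s3y, 365.9 and 273.8 for Kdm5d, and 141.9 and 165.2 for Uty. A mixture with male RNA is argued against, since the higher Xist signal was 3.09% of the lowest other array. So is an exchange of hyper replicate 4 with another group, since its Klf9 signal of 765.2 exceeded the 205.2 of the highest array outside hyper, but this was not tested for hypo_plus replicate 1. A male fetus in place of a female remains a candidate explanation, as each Y-linked gene was at least 7.71 times the highest other array on both. No other explanation was tested.

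The hormone responses differed between the goitrogen and sucrose water groups in Klf9 (−1.645) and Sema3c (−1.04), by the test of the difference itself, with dose and goitrogen both changed.

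Probe sets without a single gene name were outside the comparisons, and 362 of them passed in hypo_plus against control, 22 in hyper against control, 386 in hypo_plus against hypo (329 up and 57 down), 2 in hypo_plus against hyper and 1 in the response difference. Median centring cut the genes that rose in hypo_plus against hypo from 184 to 11, and it was not run on these probe sets. With quantile normalization 427 of these probe sets rose. That scaling did not remove the rises, but the deposited normalization as their source could not be decided. Higher background could not be decided, as those that rose gained a median of 66.8 signal units, below the 95.6 of the median probe set in hypo_plus, and 2 earlier forms of this test, on probe sets called absent, were dropped because they chose probe sets by call or near the floor. Nuclear or unspliced RNA could not be decided either, as a list of 11 nuclear-retained transcripts had a median of 0.057 with 63.6% positive. A response to hormone, the labelled difference, remains open.

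Regional genes in hypo_plus against hypo, 50 members of the striatum, GABAergic and hypothalamus lists, had a median of 0.207. A hormone effect whatever the water is argued against only for the 50 genes pooled, and the doses differ. They had −0.044 in hyper against control (−0.092 to −0.016 with 1 array left out). By list, the medians there were −0.104 for hypothalamus (5 of 22 positive), −0.036 for GABAergic genes (7 of 17) and 0.028 for striatum (8 of 12). The pooled median therefore does not decide this for the striatum genes. The array with Y-linked signal is argued against as the source, since the median was 0.217 without it. Unequal dissection may still account for it and cannot be told apart from a response under goitrogen: the hypothalamus list had a median of 0.108 with 54.5% positive, which is between the values set for either answer, and 0 of 9 dorsal cortex genes were positive (median −0.325). The preset thalamus and diencephalon list leaves it open too (median 0.553, 5 of 7 positive, adjusted p = 0.862 with an estimated correlation, array scores of −0.648 to 0.515 in hypo and −0.493 to 0.894 in hypo_plus), while the abundant dorsal genes Nfix and Neurod6 had −0.43 and −0.42, the hypothalamic peptide gene Oxt 0.40, and 3 dorsal genes and Nkx2-1 are also in other lists. In hypo_plus against control the hypothalamus list had a median of 0.15 (77.3% positive) and the dorsal cortex list −0.266 (11.1% positive). In hypo_plus against hyper they had 0.25 (90.9%) and −0.347 (0%). Both pairs lie on the side set for unequal dissection, although those limits were set for hypo_plus against hypo only. Unequal dissection may therefore bear on these comparisons too.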

How the results depend on the processing

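Alternatives without a pseudocount, by present calls, by symbol rule, with a sex marker covariate or without both arrays with Y-linked signal were chosen after seeing the data. Of the values of named genes past the threshold over all alternatives, 1846 stayed past it in the same direction, 689 lost it and 2 reversed; of the others 201 came to pass and 407 moved by more than their standard error. The reversed ones were Pafah1b1 in hypo_plus against hypo, 0.11 with the mean of probe sets, and Six3, −0.09 with 1 deposited symbol. The cause was not tested, except where fewer arrays or another threshold were used by construction. Counts follow in the order hypo, hypo_plus and hyper against control, hypo_plus against hypo, hypo_plus against hyper, and response difference (0, 100, 8, 282, 9 and 2), where they moved by over 1.5 times. Each probe set on its own gave 1400, 79, 1421, 17 and 6 probe sets from the second on, with at least 1 in 913, 51, 919, 10 and 3 genes, and the mean of probe sets 5 for hypo_plus against hyper. Genes above the median by mean level gave 221 for hypo_plus against control. Quantile normalization gave 15, 441 and 4 for hyper against control, hypo_plus against hypo and hypo_plus against hyper, and median centring 41, 5, 36, 3 and 1 from the second on. A pseudocount of 1 gave 5 and 125 for hypo_plus against control and against hypo, as did no pseudocount (5 and 125). A pseudocount of 100 gave 4, 198, 14 and 4 for hypo and hypo_plus against control, hypo_plus against hyper and the difference. Array weights gave 249, 27, 472, 87 and 11 from the second on. A trend with robust fitting gave 48 and 5 for hypo_plus against control and against hyper. Present probe sets gave 65 for hypo_plus against control, and 1 deposited symbol gave 1 for the difference. The sex marker covariate gave 169 and 5 for hypo_plus and hyper against control. Without both arrays with Y-linked signal the counts were 5, 167, 2 and 1 from hyper against control on. Using only arrays of the groups compared gave 5, 2, 67 and 4 from the second on. An unadjusted p under 0.05 with a fold of 1.5 gave 19, 38, 24, 124, 55 and 231, and an adjusted p under 0.1 gave 344, 15, 697, 20 and 5 from the second on. Leaving out 1 array gave 0 to 3, 0 to 171, 5 to 18, 85 to 473, 2 to 16 and 2 to 25. The correlation of 0.181 was 0.414 over probe sets, 0.403 over called genes, and 0.09 to 0.261 with 1 array left out. The lists past the threshold rose from 0 to 25 with a preset correlation and 1 with fry, and stayed 0 with 1 array left out. With the replicate number as a block the counts were 25 and 4 for hypo_plus against control and against hyper; the other counts moved by less than 1.5 times. The numbers do not pair the arrays: 27 same-number pairs had correlations of −0.363 to 0.434 (median −0.019, other pairs 0.008), and 5 arrays correlated best with their own number.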

Other observations

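Tests of the hypothalamus, dorsal cortex, imprinted and nuclear-retained lists were chosen after the data were seen. The exception is the dissection test in hypo_plus against hypo, whose values for the hypothalamus and dorsal cortex lists were set before its result was seen. Genes of dividing cells and intermediate progenitors, the cells that give rise to cortical neurons, had mostly lower values in hypo_plus than in hyper, but not on every array: the cell cycle score was −0.321 and −0.25 on hypo_plus replicates 4 and 5 against 0.027, 0.035 and −0.026 on replicates 1 to 3, and 0.244, −0.016, 0.068 and 0.173 on hyper replicates 1 to 4. The sign was negative in all but 1 of 23 cell cycle genes (median −0.20) and all but 1 of 11 intermediate progenitor genes (median −0.31), with adjusted p = 0.845 for each with an estimated correlation. Eomes, Sstr2 and Mfap4 of the latter list fell adjusted over the list alone, by 0.52, 0.54 and 0.53. In the same comparison 20 of 22 hypothalamus genes were positive, with a median of 0.25 and adjusted p = 0.042 with an estimated correlation over 24 tests of the added lists, and 0 of 9 dorsal cortex genes were positive (median −0.35, adjusted p = 0.243). These list tests were not recomputed under the alternatives.

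Imprinted genes were examined because Peg3 rose under goitrogen with hormone. Of 17 measured, 10 were positive in hypo_plus against hypo, with a median of 0.03 and an unadjusted camera value of 0.185 with an estimated correlation (adjusted p = 0.341), so a shift of the set was not shown or excluded. Ndn, an imprinted neuronal gene, had 0.47 (adjusted p = 0.0513). In hyper against control 3 of 17 were positive (median −0.12, adjusted p = 0.147), and in the response difference 15 of 17 were positive (median 0.19, adjusted p = 0.112), neither passing. Nuclear-retained transcripts had a median of −0.07 in hyper against control (adjusted p = 0.655).

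Other splits of the same arrays, 100 per comparison with the real one included, were counted for each number of genes. For hypo against control all 100 gave as many as the real 0, the highest other giving 65, but every split gives at least 0, so the count decides nothing about chance. A share under 0.05, the limit set beforehand, was met for hypo_plus against hypo (1 split, real 282, highest other 50) and hypo_plus against hyper (1 split, real 9, highest other 2). This argues against chance, but 100 splits cannot exclude it, and no share here is adjusted for 6 comparisons. The count of 9 was also 2 without both arrays with Y-linked signal. In hyper against control (4 splits, real 8, highest other 22) and the response difference (4 splits, real 2, highest other 5) the share was under 0.05 too. There 3 other splits gave as many, so chance is argued against only by that limit. In hypo_plus against control 2 splits gave as many as the real 100, which meets that limit as well. The other split gave 415, which points, like the 65 above, to a structure of the samples that was not tested, and 0 genes passed without control replicate 3.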
